A study of Homo sapiens with 16 samples.

How the data were processed

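Gene expression was measured by poly(A) RNA sequencing of 16 libraries of LX-2, an immortalised line of human hepatic stellate cells. Per the labels' protocols, cells were cultured for 24 h and then given 100 ng/mL TWEAK or its PBS vehicle for 2 h, and mRNA was isolated with oligo(dT) beads, fragmented and primed at random. The labels give 4 groups of 4 biological replicates: wild type with vehicle (WT), wild type with TWEAK, a CRISPR/Cas9 knockout of Fn14alpha and a knockout of total Fn14. Nothing else says how the replicates were separated, so p-values measure the spread between these cultures or samples, which may be technical. Whether a knockout is a single clone or a pool is not given in the sources used here, and each genotype is also a cell line of its own.

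The deposited table holds, for each of 61806 Ensembl genes, a raw read count per library with no normalization. Per the submitters' processing notes, the tools were FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 with no version, and the genome builds named are GRCh38.p13 and hg38. The notes give these names without their roles. Strand setting, annotation release and the treatment of reads that map to several genes are not given in the sources used here. The same table holds FPKM values that the authors made from those counts, the exonic size of each gene and the library total, per the file headers and the values. Gene positions are those of the deposited table, and the exons of TNFRSF12A were read from a GENCODE annotation of GRCh38. A count per gene cannot separate the isoforms of Fn14. All columns of sample values in the table were used.

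Total counts per library ran from 13335919 to 16888606. Replicate pairs within a group were compared by a chi-square test of their counts over genes with at least 100 counts. The chi-square per degree of freedom of the 24 pairs ran from 2.30 to 39.0, so no pair agreed within sampling noise and each library was counted once. Counts were computed on with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Plots were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

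Genes were tested with edgeR's quasi-likelihood test (two-sided) on the deposited counts, with TMM scaling, filterByExpr by group, robust estimation and 1 mean per group over all 16 libraries. The filter left 16029 genes, and the common dispersion was 0.00750. A gene was called at a Benjamini-Hochberg false discovery rate of 0.05 over the genes tested. The comparisons were TWEAK minus WT, Fn14alpha knockout minus WT, Fn14 knockout minus WT, and Fn14 knockout minus Fn14alpha knockout. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Levels are FPKM as mean ± SD of 4 libraries. Fold values given without a bound or counting interval come from the log2 fold change of the edgeR fit. They can differ from the ratio of the FPKM levels printed beside them. TNFRSF12A was also tested by an exact two-sided permutation test of 4 libraries against 4. Y-linked genes and XIST were kept in the fits and counts and are not reported one by one.

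Symbols of the lists that the table lacks were looked up by current or older name in a table of gene identifiers. 27 gene lists were tested with limma's camera (two-sided) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists of 1 comparison. The hepatocyte list had only 2 measured members and no camera test. Each list was also tested with a correlation estimated from the residuals, and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. The lists cover NF-kB targets, cytokines, TNF receptor signalling, immediate early genes, stellate cell matrix and quiescence, matrix-degrading enzymes, targets of TGF-beta, YAP, interferon, p53, ATF4, SREBP and NRF2, antigen presentation, the cell cycle, hypoxia, growth factors and adhesion. They also cover markers of hepatocytes, endothelium, cholangiocytes and leukocytes, the genes beside TNFRSF12A, and 3 lists on RNA quality. Several lists share members.

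The samples of each comparison, the tests, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took TNFRSF12A and, among called genes with a mean of at least 2 FPKM in 1 of the groups and all 4 libraries of one group above all 4 of the other, the 12 with the largest positive and the 12 with the largest negative log2 fold change. For each list described it also took up to 4 called members with the smallest adjusted p and up to 2 that did not pass. After the data had been seen, that last part was narrowed to up to 3 called members of the lists that camera called and to no members that did not pass, because the values of the latter lay near 0 and changed sign under many alternatives. Some genes that the rule takes are not reported here. In each gene named in a comparison, all 4 libraries of one group lay above all 4 of the other, except TNFRSF12A with TWEAK. For a single gene not picked for it, chance gives such a separation for 4 against 4 with an exact p of 0.0286. The rule itself required the separation of the genes with the largest differences, so there it adds no support.

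Alternatives were DESeq2 size factors or total counts in place of TMM, no filter or a filter of at least 5 CPM in at least 4 libraries, the DESeq2 Wald test, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), a fit of only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. 2 alternatives were added after the data had been seen: leaving out WT replicate 4 and Fn14 knockout replicate 1 together, and removing from each gene the median log2 fold change of 50 neighbouring genes as an offset in the fit. A test of 1276 Gene Ontology terms of 15 to 300 measured genes, taken from the deposited annotation, was also added then. In the search for libraries apart from their group, groups whose libraries were all at 0 counts were first picked up through rounding error and were removed from it once this was noticed. Of the patterns weighed for technical causes, that of NF-kB targets between the knockouts was chosen after the result of its list had been seen. It replaced a pattern on all TWEAK-induced genes, whose list had not passed and whose tests were not run, and 1 further prediction was dropped because no table could decide it.

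The steps were tested on simulated data. For TWEAK against WT, with 16029 genes, edgeR recovered 22% of 50 genes changed 1.25-fold, 70% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 100% of 50 changed 4-fold, and 12 of 156 calls (7.69%) were unchanged genes. In the Fn14alpha knockout comparison, a simulated log2 shift of −0.5, the same for all 853 genes of a chromosome, gave 580 calls and a median of −0.48. After the local median was removed 0 calls and a median of −0.0007 were left. Shifts that differ between neighbouring genes were not simulated. Because both knockouts were compared with the same WT libraries, unchanged groups were simulated against those libraries in 20 draws, and WT was also split into parts of 2 libraries in 6 ways. Both were extended to the genes that TWEAK changed most after the data had been seen.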

Results

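LX-2 is an immortalised line of human hepatic stellate cells, the liver cells that deposit fibrillar matrix when activated. Poly(A) RNA was sequenced from 4 groups of 4 replicates: wild-type cells given vehicle (WT), wild-type cells given the cytokine TWEAK at 100 ng/mL for 2 h, a CRISPR/Cas9 knockout of Fn14alpha and a CRISPR/Cas9 knockout of total Fn14. Fn14, the receptor of TWEAK, is the product of TNFRSF12A, and the title of the series concerns an isoform of it that acts without TWEAK. Total counts ran from 14273840 to 16888606 in WT, 13335919 to 15846385 with TWEAK, 13741703 to 15300005 in the Fn14alpha knockout and 14092328 to 16417325 in the Fn14 knockout (n = 4 libraries each). In a principal component analysis of the 16 libraries, the first component (51.0% of the variance) parted the Fn14 knockout from the other groups and the following one (23.8%) the Fn14alpha knockout. On component 3 (5.44%), WT replicate 4 (37.0) and Fn14 knockout replicate 1 (24.5) lay apart from the other 14 libraries (−19.9 to 10.4).

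TNFRSF12A (ENSG00000006327, GRCh38 chromosome 16, 3018445 to 3022383, plus strand) was lower in all 8 knockout libraries than in all 8 wild-type libraries. Its level was 128 ± 6.29 FPKM in WT, 130 ± 7.07 with TWEAK, 59.3 ± 6.43 in the Fn14alpha knockout and 33.6 ± 2.77 in the Fn14 knockout (SD, n = 4). By the log2 fold change of the edgeR fit, 45.3% of the WT level was left in the Fn14alpha knockout (−1.14 ± 0.08 SE, edgeR adjusted p = 2.16e-11). In the Fn14 knockout 28.5% was left (−1.81 ± 0.08, edgeR adjusted p = 2.85e-15). The Fn14 knockout was also lower than the Fn14alpha knockout (−0.67 ± 0.08, edgeR adjusted p = 9.54e-08). Each of these had an exact permutation p of 0.0286, the smallest that 70 splits of 4 against 4 can give (0.0381 after adjustment over 4 tests). With TWEAK the difference was 0.08 ± 0.07 (edgeR adjusted p = 0.564, exact p = 0.143, adjusted exact p = 0.143). The annotation holds 7 transcripts of the gene. TNFRSF12A-201 has 4 exons, and TNFRSF12A-202 has 3 and lacks the exon at 3021215 to 3021319. The deposited counts sum over all of them, so they do not show which transcripts remained, and an edited allele can still give mRNA. Several genes beside TNFRSF12A were also lower in the Fn14alpha knockout, as given below. Whether a shift of that region contributes to the level of TNFRSF12A was not tested.

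**Figure D1:**
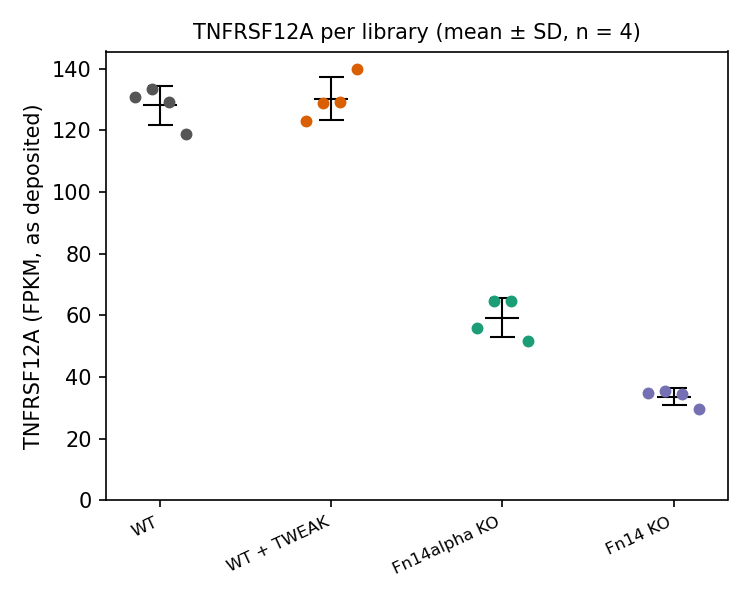
Deposited FPKM of TNFRSF12A in each library by group (points), with the group mean and SD (n = 4). WT libraries lay between 119 and 133, TWEAK libraries between 123 and 140, Fn14alpha knockout libraries between 51.8 and 64.7 and Fn14 knockout libraries between 29.5 and 35.6 FPKM.

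The comparison of TWEAK with vehicle asked which transcripts of wild-type cells change within 2 h. TRAF1 (ENSG00000056558, chromosome 9), an adaptor of TNF receptor signalling, rose 26.9-fold, from 1.56 ± 0.237 to 40.3 ± 2.09 FPKM (SD, n = 4; log2 fold change 4.75 ± 0.12 SE, edgeR adjusted p = 1.64e-18). BIRC3, an inhibitor of apoptosis, rose 11.3-fold to 48.2 ± 3.56 FPKM. The cytokine subunit IL23A, the adhesion molecule VCAM1 and the TNF receptor family member TNFRSF9 rose 4.79-, 4.47- and 4.08-fold. RNF19B, NRP2, LIPG, FGD6, MMP9, S1PR1 and ST6GALNAC5 rose 4.00- to 3.25-fold, MMP9, a gelatinase, from 19.0 ± 0.442 to 63.4 ± 4.29 FPKM.

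Decreases were smaller. FST, which encodes the activin antagonist follistatin, fell from 15.5 ± 2.26 to 6.11 ± 0.710 FPKM (log2 fold change −1.29 ± 0.11, edgeR adjusted p = 9.76e-09). The bradykinin receptor gene BDKRB2 fell by 1.18 and the apelin gene APLN by 1.01 on the log2 scale, and CAVIN2, SYTL2, MEST, CCDC71L, STC1, TMEFF2 and STC2 by between 0.94 and 0.72. Among genes that met the rule for named genes, JCHAIN showed the largest decrease (−1.61 ± 0.35, edgeR adjusted p = 0.00562). It did not pass with the DESeq2 Wald test (adjusted p = 0.178) or with limma on log2(FPKM + 0.1) (adjusted p = 0.0708, range over its alternatives 2.15e-09 to 0.178). PIR (−0.78 ± 0.20, edgeR adjusted p = 0.0193) did not pass without WT replicate 4 (adjusted p = 0.0978), TWEAK replicate 1 (0.0516) or TWEAK replicate 2 (0.0728), with a range over its alternatives of 8.98e-04 to 0.0978.

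Targets of NF-kB, the transcription factor family activated downstream of TNF receptors, rose together. Of 38 measured targets 29 were higher, 0 lower and 9 did not pass (32 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.59 (camera adjusted p = 2.71e-42). NFKB2 rose 2.96-fold beside TRAF1 and BIRC3. Chemokines and cytokines were higher in 18 of 22 cases, with 0 lower (18 higher and 2 lower adjusted over the list alone; median 0.86, camera adjusted p = 1.15e-16). CXCL3, CXCL1 and CXCL5, neutrophil-attracting chemokines of neighbouring genes on chromosome 4, rose 2.74-, 2.43- and 2.08-fold, CXCL5 from 300.3 ± 17.1 to 600.5 ± 29.2 FPKM. Reads shared between these similar genes cannot be ruled out from the counts. Among TNF receptor family and NF-kB signalling parts, 19 of 37 were higher and 0 lower (20 higher and 1 lower adjusted over the list alone; camera adjusted p = 5.34e-18). Immediate early genes were higher in 10 of 33 cases and lower in 1 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.25e-07), among them JUNB, CCN1 and FOSL1 at 1.77-, 1.79- and 1.80-fold. These 4 lists also passed with an estimated correlation.

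A further 4 lists were called by camera and not with an estimated correlation. YAP and TEAD targets were higher in 9 of 21 cases and lower in 1 (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 9.97e-07, adjusted p = 0.237 with an estimated correlation), led by the kinase gene NUAK2 at 2.58-fold, with CCN1 and GADD45A. Adhesion molecules and integrins were higher in 5 of 29 cases (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.46e-04, adjusted p = 0.256 with an estimated correlation), with VCAM1, ICAM1 at 2.03-fold and CD44 at 1.68-fold. Cholesterol synthesis and SREBP targets were lower in 5 of 30 cases and higher in 1 (1 higher and 13 lower adjusted over the list alone; median −0.16, camera adjusted p = 4.84e-05, adjusted p = 0.237 with an estimated correlation). Among the lower ones were the sterol synthesis genes MSMO1 (−0.28 ± 0.07) and HSD17B7 (−0.37 ± 0.09). MSMO1 did not pass without TWEAK replicate 1 (adjusted p = 0.0548) or TWEAK replicate 3 (0.0750), nor HSD17B7 without TWEAK replicate 3 (0.0605). Over all alternatives their adjusted p ran from 0.00218 to 0.0750 and from 0.00375 to 0.0605. Ribosomal protein genes had a median of −0.11 with 0 of 78 passing over all genes or adjusted over the list alone (camera adjusted p = 1.22e-04, adjusted p = 0.618 with an estimated correlation, 0.275 without WT replicate 4, range over all alternatives 4.42e-06 to 0.618). WT replicate 4 had a mean of 8.63 log2 CPM over these genes, against 8.30 to 8.31 in the other WT libraries.

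In all, edgeR's quasi-likelihood test called 1101 of 16029 genes, 773 higher and 328 lower (70.2% higher). With total counts in place of TMM 43.9% of the calls were higher, and limma on log2(FPKM + 1) called 512 higher and 637 lower. At an absolute log2 fold change of at least 1 there were 119 higher and 27 lower genes, and without WT replicate 4 and Fn14 knockout replicate 1 there were 1353 calls. The other 18 lists with a camera test, markers of other cell types and the other RNA quality lists included, had adjusted p between 0.0653 (NRF2 targets) and 0.958 (cell cycle). Median and mean differed in sign for matrix-degrading enzymes, p53 targets and growth factors.

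The Fn14alpha knockout was compared with WT to see what differs, without added TWEAK, in the line labelled as lacking Fn14alpha. TNFRSF11B (ENSG00000164761, chromosome 8), which encodes the decoy receptor osteoprotegerin, was 44.6-fold higher, at 12.5 ± 1.06 against 0.273 ± 0.137 FPKM (SD, n = 4; log2 fold change 5.48 ± 0.19 SE, edgeR adjusted p = 1.48e-16). SHISA3, CCN3, TBX1 and the endothelin gene EDN1 were 15.8-, 9.31-, 8.08- and 7.97-fold higher. INHBB, ANKRD1, IGFBP5, DMBX1, SPINT1, RGS4 and ARHGDIG were 6.97- to 5.30-fold higher. The chemokine CXCL5 was 12.02-fold lower, at 25.6 ± 1.63 against 300.3 ± 17.1 FPKM (−3.59 ± 0.08, adjusted p = 4.71e-20), and the aminopeptidase gene ANPEP was 34.7-fold lower.

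Of the 12 genes with the largest decreases among those that met the rule for named genes, 6 lay on the X chromosome: PAGE1, MAGEC2, SPANXB1, SSX1, IL13RA2 and HMGN5. MAGEC2, a cancer/testis antigen gene, fell from 30.8 ± 3.08 to 0.430 ± 0.127 FPKM, and IL13RA2 was 48.6-fold and HMGN5 11.6-fold lower. PAGE1 and SPANXB1 had 1 count each and SSX1 3 counts over the 4 knockout libraries, giving ratios to WT of 0.00865 (95% counting interval 2.17e-04 to 0.0491), 0.0104 (2.61e-04 to 0.0592) and 0.0133 (0.00273 to 0.0395). MT1L, a metallothionein pseudogene, had 2 counts (ratio 0.0267, interval 0.00318 to 0.0996). These families have near-identical members, so their counts are uncertain where reads are shared, and the intervals cover counting error only. NAALADL1, the proteoglycan gene LUM and JCHAIN were 18.8-, 14.7- and 12.8-fold lower. Chromosome medians were taken only over tested genes with at least 2 log2 CPM. The median log2 fold change was −0.69 for 390 such genes on X, −0.48 for 629 on chromosome 12 and −0.26 for 466 on chromosome 9. Of these chromosome 12 genes, 80.1% were called lower. Removing the median of neighbouring genes moved MAGEC2, SPANXB1, IL13RA2, HMGN5 and LUM by more than 1.5-fold toward 0, and each still passed.

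NF-kB targets were lower on balance: 23 of 38 were lower, 6 higher and 9 did not pass (6 higher and 23 lower adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.00130, 0.0316 with an estimated correlation). CXCL1 and CXCL3 were 2.72- and 2.11-fold lower, whereas VCAM1 was 3.87-fold higher (1.95 ± 0.10, edgeR adjusted p = 1.93e-13). p53 targets were lower in 17 of 27 cases and higher in 3 (3 higher and 19 lower adjusted over the list alone; camera adjusted p = 1.81e-04, 0.00988 with an estimated correlation), with the cell cycle inhibitor CDKN1A 2.62-fold, MDM2 1.68-fold and FAS 2.26-fold lower. MDM2, on chromosome 12, went from −0.75 to −0.17 (adjusted p = 0.0252, range over its alternatives 5.95e-44 to 0.0252) with the median of neighbouring genes removed. NRF2 targets were lower in 15 of 25 cases and higher in 1 (1 higher and 18 lower adjusted over the list alone; camera adjusted p = 2.57e-04, 0.0316 with an estimated correlation), with MGST1 4.62-fold and AKR1C1 7.33-fold lower. MGST1 went from −2.21 to −1.54 with that median removed, and AKR1C1 has close paralogs.

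Cholesterol synthesis and SREBP targets were lower in 26 of 30 cases and higher in 3 (3 higher and 26 lower adjusted over the list alone; median −0.46, camera adjusted p = 1.69e-08, adjusted p = 0.0594 with an estimated correlation). HMGCS1, MSMO1 and NSDHL, enzymes of the sterol pathway, were 2.26-, 2.24- and 2.07-fold lower. NSDHL, on the X chromosome, went from −1.05 to −0.43 with the median of neighbouring genes removed (adjusted p = 7.48e-05, range over its alternatives 9.87e-41 to 7.48e-05). Chemokines and cytokines were lower in 14 of 22 cases and higher in 4 (4 higher and 14 lower adjusted over the list alone; median −0.73, camera adjusted p = 4.74e-04, adjusted p = 0.0883 with an estimated correlation). Interferon response genes were lower in 18 of 35 cases and higher in 2 (2 higher and 18 lower adjusted over the list alone; median −0.61, camera adjusted p = 4.74e-04, adjusted p = 0.0883 with an estimated correlation), with BST2, TRIM22 and OAS3 6.47-, 4.56- and 1.98-fold lower. OAS3 (log2 fold change −0.99) lies on chromosome 12, where the median was −0.48 in this comparison. YAP and TEAD targets were higher in 12 of 21 cases and lower in 2 (12 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00137, adjusted p = 0.415 with an estimated correlation), and TGF-beta and SMAD targets higher in 9 of 22 cases and lower in 4 (11 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0315, adjusted p = 0.0767 with an estimated correlation). The growth factor gene TGFB2, CCN2, PMEPA1 and CCN1 were 4.70-, 3.63-, 3.10- and 2.02-fold higher. Of 10 measured neighbours of TNFRSF12A, 6 were lower, among them MMP25, IL32 and FLYWCH2, and 4 did not pass (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0377, adjusted p = 0.348 with an estimated correlation). That call was lost without WT replicate 3 (adjusted p = 0.0630), without Fn14alpha knockout replicate 1 (0.0521) and with the median of neighbouring genes removed (0.406), and its adjusted p ran from 1.77e-04 to 0.406 over all alternatives.

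edgeR's quasi-likelihood test called 6771 of 16029 genes between the Fn14alpha knockout and WT, 3207 higher and 3564 lower, 504 and 725 of them at an absolute log2 fold change of at least 1. With total counts the split was 3646 higher and 3232 lower (53.01% higher against 47.4%). With the median of neighbouring genes removed there were 4980 calls, of which 3896 were among the 6771 in the same direction and 98 in the other, and without the 2 libraries that lay apart there were 7226. The other 17 lists with a camera test had adjusted p between 0.112 (antigen presentation; leukocyte markers) and 0.925, with medians, means or tests of differing sign for quiescent stellate cell markers, growth factors, endothelial markers and cholangiocyte markers. Mitochondrial mRNAs had a median of −0.29 (adjusted p = 0.251) and ribosomal protein genes of −0.06 (0.250).

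The Fn14 knockout was compared with WT to see what differs in the line labelled as lacking total Fn14. Chemokine transcripts that were abundant in WT were far lower: CXCL8 (ENSG00000169429, chromosome 4), a neutrophil attractant, was at 0.400 ± 0.177 against 107 ± 14.5 FPKM (SD, n = 4; log2 fold change −7.91 ± 0.17 SE, edgeR adjusted p = 1.87e-19). CXCL6 and CXCL1 were 189- and 126-fold lower, CXCL5 56.8-fold and the cytokine IL1B 97.3-fold. The complement gene C3 was 216-fold lower (12 counts over the knockout libraries) and DPYSL4 127-fold (7 counts). In the other direction, COL6A3 (ENSG00000163359, chromosome 2), a chain of collagen VI, was 33.0-fold higher, at 52.2 ± 6.37 against 1.71 ± 0.299 FPKM (5.05 ± 0.12, edgeR adjusted p = 1.00e-19). The gap junction gene GJA1, the neurotrophin receptor gene NGFR, SLC24A3, KCNS3 and TRBC2 were 28.7-, 24.3-, 33.4-, 19.2- and 46.8-fold higher and the protease gene ADAMTS2 405-fold (5 counts in WT), and RGS4 was at 40.6 ± 2.96 against 2.20 ± 0.320 FPKM.

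Several of the largest differences had 3 or fewer counts over the 4 libraries of one group. PTPN20 and S100A7 had 0 counts in WT and were at least 208-fold and at least 55.8-fold higher in the Fn14 knockout, taking a floor of 3 counts over the group. S100A9 and S100A8, subunits of calprotectin, had 1 count each in WT (ratios 205, interval 36.4 to 8151, and 179, interval 31.7 to 7097). KIRREL2 and MT1L had 0 counts in the knockout and were at least 141-fold and at least 26.3-fold lower. MGST1, CSF3, JCHAIN and SSX1 had 1 count each in the knockout and PCDHB17P 2, with ratios to WT of 4.98e-04 (interval 1.26e-05 to 0.00278), 0.00120 (3.03e-05 to 0.00669), 0.00339 (8.55e-05 to 0.0190), 0.00423 (1.07e-04 to 0.0238) and 0.00521 (6.29e-04 to 0.0190).

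Of 38 NF-kB targets, 36 were lower in the Fn14 knockout, 0 higher and 2 did not pass (0 higher and 37 lower adjusted over the list alone), with a median of −1.98 (camera adjusted p = 3.85e-25). CXCL3 was 39.0-fold lower beside IL1B and CXCL1. Chemokines and cytokines were lower in 20 of 22 cases and higher in 1 (1 higher and 20 lower adjusted over the list alone; median −3.67, camera adjusted p = 2.40e-16). Interferon response genes were lower in 26 of 35 cases and higher in 1 (1 higher and 28 lower adjusted over the list alone; median −1.06, camera adjusted p = 6.03e-09), with IFI44, OAS3 and HERC6 25.3-, 3.79- and 3.23-fold lower. p53 targets were lower in 16 of 27 cases and higher in 3 (3 higher and 16 lower adjusted over the list alone; median −0.25, camera adjusted p = 0.00789), with GDF15 9.68-fold, FAS 2.93-fold and CDKN1A 2.46-fold lower. These 4 lists passed with an estimated correlation too (adjusted p 2.60e-06, 0.00143, 0.0133 and 0.0252).

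Antigen presentation genes were lower in 14 of 23 cases and higher in 3 (3 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.00789, adjusted p = 0.325 with an estimated correlation), with PSMB9, ERAP2 and ERAP1 2.47-, 2.14- and 1.89-fold lower. Matrix-degrading enzymes were lower in 13 of 25 cases and higher in 6 (7 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.0487, adjusted p = 0.131 with an estimated correlation). The collagenase gene MMP1 was 66.2-fold, MMP9 6.46-fold and the plasminogen activator gene PLAU 6.07-fold lower. The call of this list was lost without WT replicate 3 (adjusted p = 0.0562), without Fn14 knockout replicate 1 (0.0571), without both libraries that lay apart (0.0541) and with the replicate number as a block (0.0515), with a range over all alternatives of 7.16e-11 to 0.131. YAP and TEAD targets were higher in 12 of 21 cases and lower in 5 (12 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.453 with an estimated correlation), with ANKRD1, TGFB2 and CCDC80 15.9-, 9.73- and 2.14-fold higher. Cholesterol synthesis and SREBP targets were higher in 17 of 30 cases and lower in 4 (19 higher and 4 lower adjusted over the list alone; median 0.23, camera adjusted p = 0.0125, adjusted p = 0.403 with an estimated correlation). SQLE and FDPS were 1.60- and 1.57-fold higher, and FDPS did not pass with the median of neighbouring genes removed (0.12, adjusted p = 0.183; range over its alternatives 6.28e-17 to 0.183).

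edgeR's quasi-likelihood test called 8472 of 16029 genes between the Fn14 knockout and WT, 4256 higher and 4216 lower, 673 and 1398 of them at an absolute log2 fold change of at least 1. With total counts the split was 3189 higher and 5681 lower (35.9% higher against 50.2%), with the median of all genes at −0.12, and limma on log2(FPKM + 1) gave 2769 higher and 4477 lower. Chromosome medians of the log2 fold change, over genes with at least 2 log2 CPM, were 0.45 for 13 and for 22, 0.38 for 3, 0.30 for 20, 0.27 for 17 and −0.22 for 2. Removing the median of neighbouring genes left 6736 calls, of which 5393 were among the 8472 in the same direction and 151 in the other. It moved ADAMTS2, SLC24A3 and IL1B by more than 1.5-fold toward 0, and each still passed. Without the 2 libraries that lay apart there were 8907 calls. The other 18 lists with a camera test had adjusted p between 0.0874 (ATF4 targets) and 0.994, and medians, means or tests differed in sign for immediate early genes, quiescent stellate cell markers, histones and the neighbours of TNFRSF12A.

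**Figure D2:**
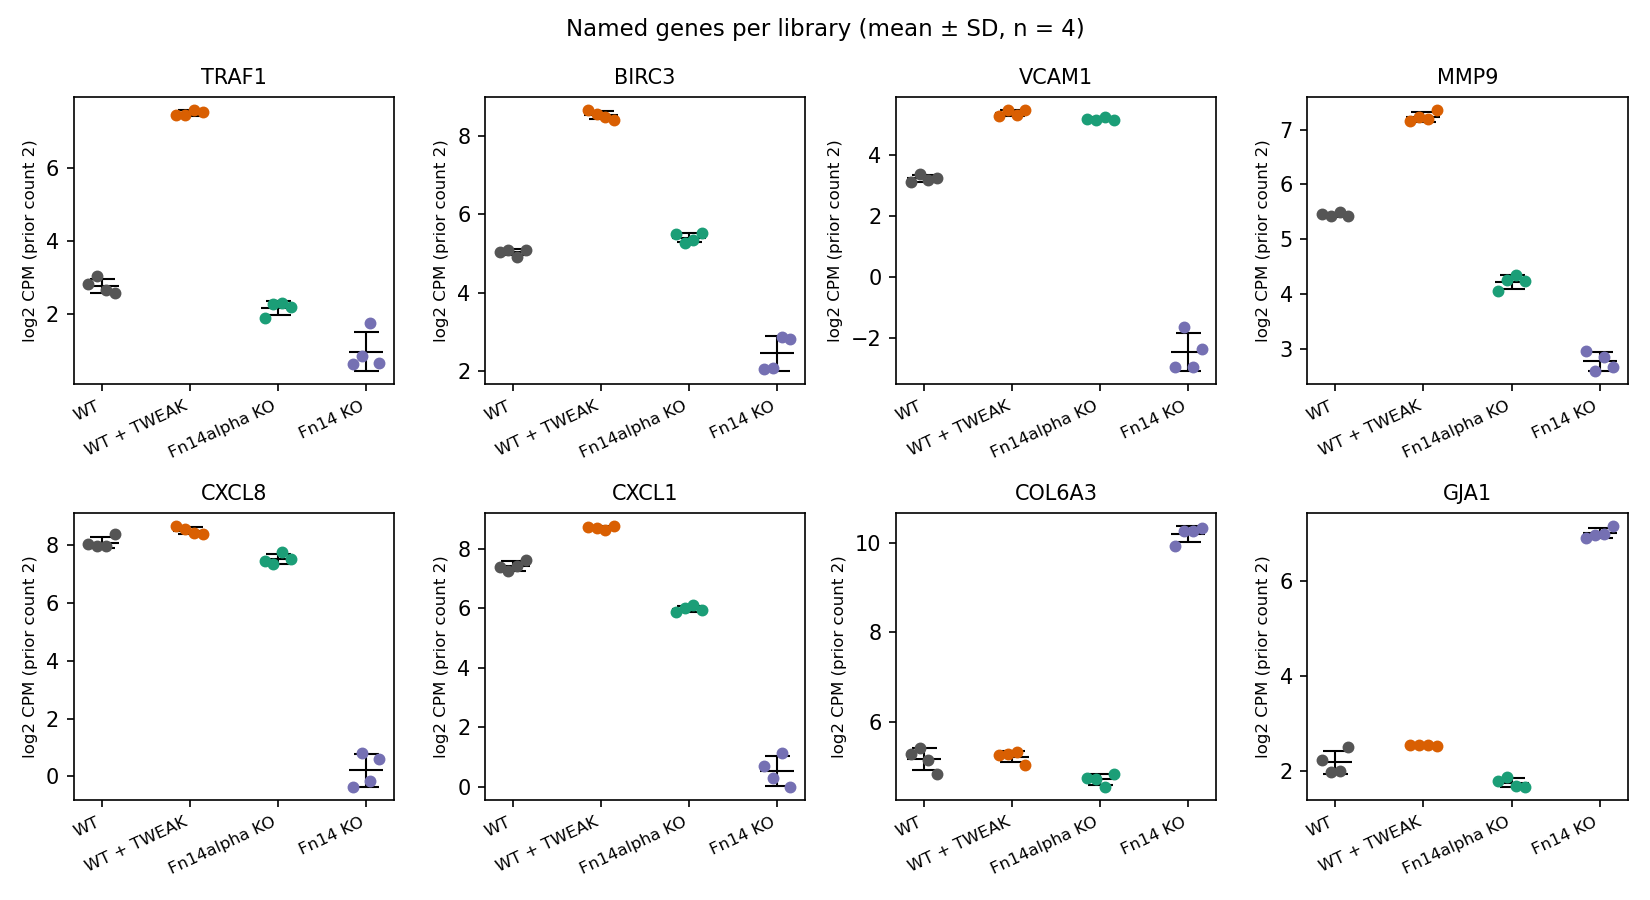
Level of 8 named genes in each library (points; log2 CPM with a prior count of 2), with group mean and SD (n = 4). TRAF1, BIRC3, VCAM1 and MMP9 were higher with TWEAK than with vehicle, CXCL8 and CXCL1 were lowest in the Fn14 knockout, and COL6A3 and GJA1 were highest there.

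The knockouts were then compared with each other (Fn14 minus Fn14alpha), in which the WT libraries enter only through the scaling and the dispersion of the fit. VCAM1 (ENSG00000162692, chromosome 1) was 473-fold lower in the Fn14 knockout, at 0.01 ± 0.0141 against 6.31 ± 0.238 FPKM (SD, n = 4; 4 and 2228 counts; log2 difference −8.88 ± 0.22 SE, edgeR adjusted p = 6.05e-20). CXCL8, C3, TBX1, EEF1A2 and JPH3 were 161.5-, 151-, 186-, 147- and 144-fold lower, and KIRREL2, TUBB4A and ARHGDIG, with 0 counts in the Fn14 knockout, at least 309-, 166- and 145-fold. UCA1, TLX1 and PCDHB17P had 2, 1 and 2 counts there (ratios 0.00154, interval 1.86e-04 to 0.00556; 0.00155, interval 3.91e-05 to 0.00865; and 0.00449, interval 5.42e-04 to 0.0163). Higher in the Fn14 knockout were COL6A3, GJA1, the gelatinase gene MMP2 and ANPEP at 45.7-, 39.3-, 25.9- and 133-fold, with TRBC2, SLC24A3 and NGFR at 28.3-, 21.2- and 18.7-fold. PTPN20, S100A8 and S100A7 had 0 counts in the Fn14alpha knockout and were at least 192-, 55.1- and 51.6-fold higher, ADAMTS2 had 1 count (ratio 1913, interval 343 to 75613) and S100A9 3 counts (ratio 63.3, interval 21.4 to 309.7).

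NF-kB targets were lower in the Fn14 knockout than in the Fn14alpha knockout in 34 of 38 cases and higher in 1 (1 higher and 34 lower adjusted over the list alone; median −1.46, camera adjusted p = 5.64e-19, 1.23e-05 with an estimated correlation). IL1B and ICAM1 were 46.0- and 32.7-fold lower beside VCAM1. Chemokines and cytokines were lower in 18 of 22 cases and higher in 1 (1 higher and 18 lower adjusted over the list alone; median −2.86, camera adjusted p = 6.27e-12, 0.00575 with an estimated correlation), with CXCL1 46.4-fold and CXCL3 18.5-fold lower. Interferon response genes were lower in 21 of 35 cases and higher in 4 (4 higher and 22 lower adjusted over the list alone; camera adjusted p = 0.00251, adjusted p = 0.240 with an estimated correlation), with IFI44 9.70-fold and OAS3 1.91-fold lower and TRIM22 2.39-fold higher. Cholesterol synthesis and SREBP targets were higher in 24 of 30 cases and lower in 2 (24 higher and 2 lower adjusted over the list alone; median 0.76, camera adjusted p = 7.13e-08, adjusted p = 0.117 with an estimated correlation), with HMGCS1, MSMO1 and SQLE 2.69-, 2.35- and 2.11-fold higher.

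A further 3 lists were called between the knockouts with a camera adjusted p of 0.0480 each. Stellate cell activation and matrix genes were higher in 24 of 39 cases and lower in 15 (24 higher and 15 lower adjusted over the list alone; adjusted p = 0.581 with an estimated correlation). COL6A3 and SPARC (2.43-fold) were higher and the proteoglycan gene BGN was 20.6-fold lower. ATF4 and unfolded protein response genes were higher in 16 of 30 cases and lower in 5 (16 higher and 6 lower adjusted over the list alone; adjusted p = 0.581 with an estimated correlation), with ALDH1L2 2.79-fold and PSAT1 2.72-fold higher and the chaperone gene PDIA4 1.48-fold lower. Of 5 measured leukocyte and macrophage markers 4 were higher and 0 lower (4 higher and 0 lower adjusted over the list alone; adjusted p = 0.328 with an estimated correlation): LAPTM5 at 6.58 ± 0.598 FPKM, CSF1R at 0.685 ± 0.0238 and CD68 at 0.425 ± 0.0666 in the Fn14 knockout were 4.70-, 5.95- and 3.27-fold higher. The call of the ATF4 list was lost without Fn14alpha knockout replicate 1 (adjusted p = 0.0565) or 4 (0.0527) or Fn14 knockout replicate 1 (0.0772), and that of the leukocyte list without Fn14alpha knockout replicate 2 (0.0663) or Fn14 knockout replicate 1 (0.0772) or 2 (0.0550). Both were also lost without both libraries that lay apart (0.0889 each). With the replicate number as a block the ATF4, leukocyte and stellate cell lists all lost their calls (0.0508 each). Over all alternatives the adjusted p ran from 5.81e-06 to 0.581 for the ATF4 list, from 1.36e-07 to 0.328 for the leukocyte list and from 1.29e-07 to 0.581 for the stellate cell list.

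edgeR's quasi-likelihood test called 9489 of 16029 genes between the knockouts, 4923 higher and 4566 lower in the Fn14 knockout, 958 and 1487 of them at an absolute log2 difference of at least 1. With total counts the split was 3666 higher and 6166 lower (37.3% higher against 51.9%), with the median of all genes at −0.15, and limma on log2(FPKM + 1) gave 3213 and 4870. With the median of neighbouring genes removed, 5774 of the 9489 calls passed in the same direction and 260 in the other, SLC24A3 and JPH3 moved by more than 1.5-fold toward 0 and BGN away from 0, and leaving out the 2 libraries apart gave 10031. The other 19 lists with a camera test had adjusted p between 0.177 (histones) and 0.920. Among them, medians, means or tests differed in sign for immediate early genes, TGF-beta targets, NRF2 targets, endothelial markers, neighbours of TNFRSF12A and ribosomal protein genes.

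Lists that camera called in no comparison were markers of quiescent stellate cells, the cell cycle, hypoxia and glycolysis, growth factors, endothelium and cholangiocytes, mitochondrial mRNAs and histones. In the order TWEAK, Fn14alpha knockout, Fn14 knockout and difference of the knockouts, the camera adjusted p was 0.389, 0.503, 0.812 and 0.632 for quiescent stellate cell markers, 0.958, 0.400, 0.674 and 0.403 for the cell cycle, and 0.580, 0.251, 0.674 and 0.657 for hypoxia and glycolysis. For growth factors it was 0.397, 0.925, 0.374 and 0.437, for endothelial markers 0.460, 0.781, 0.397 and 0.657 with 7 measured members, and for cholangiocyte markers 0.421, 0.925, 0.674 and 0.817 with 7 measured members. Mitochondrial mRNAs had 0.0742, 0.251, 0.812 and 0.403, and histones 0.116, 0.249, 0.674 and 0.177. Of 32 growth factor genes, 13 were higher and 14 lower in the Fn14alpha knockout and 11 and 16 in the Fn14 knockout, and 12 of 47 histone genes were higher and 12 lower in the Fn14 knockout. The 2 measured hepatocyte markers had 0 calls with TWEAK, 1 lower in the Fn14alpha knockout, and 1 higher and 1 lower in the Fn14 knockout.

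**Figure D3:**
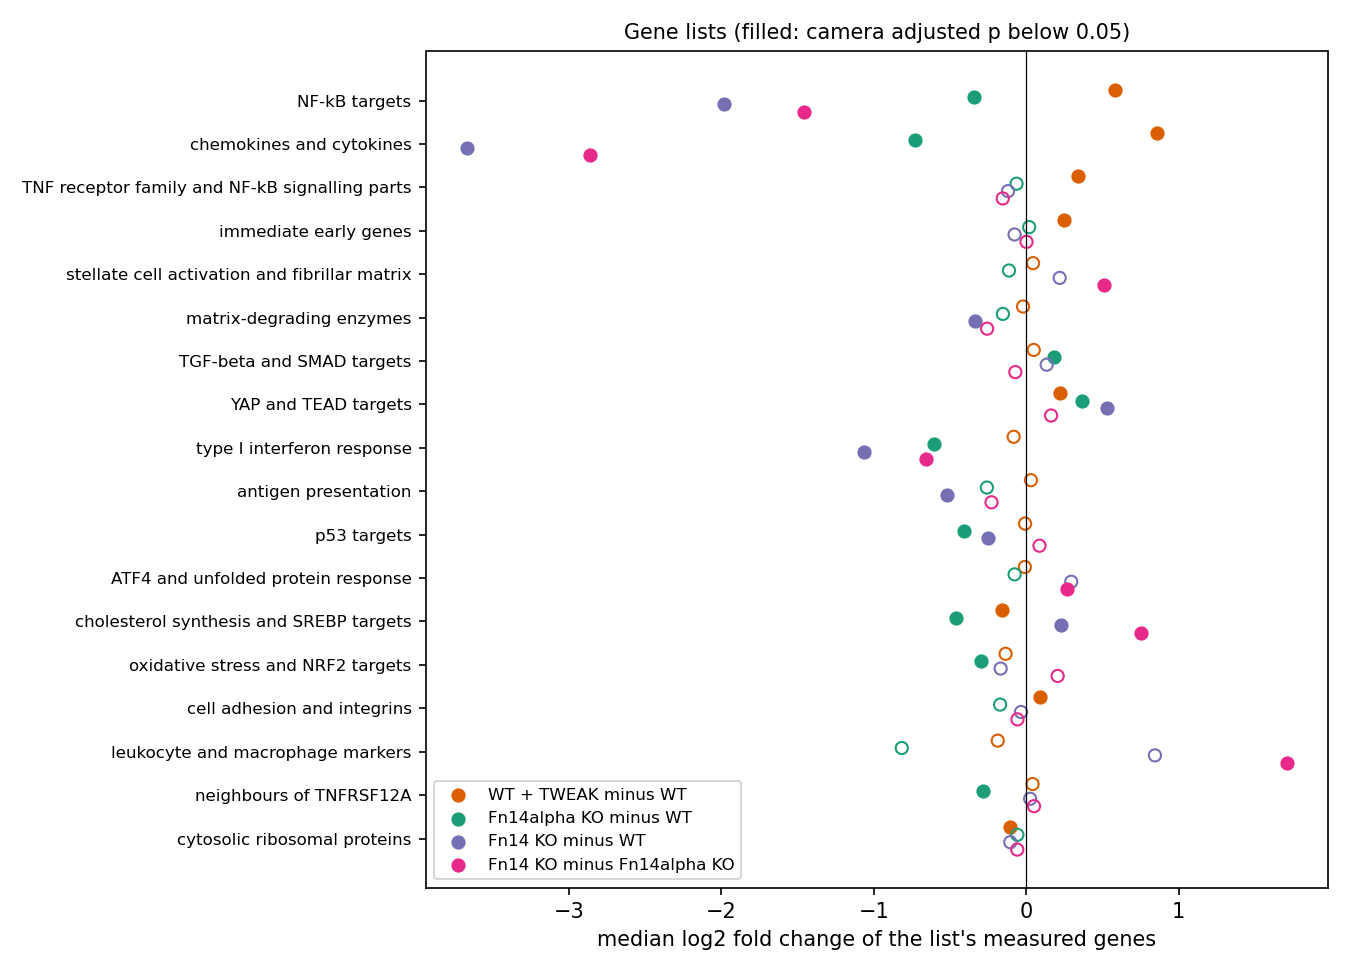
Median log2 fold change of the measured genes of each list that camera called in 1 or more of the 4 comparisons, with filled points where the camera adjusted p was below 0.05 and open points where it was not. NF-kB targets had medians of 0.59 with TWEAK, −0.34 in the Fn14alpha knockout and −1.98 in the Fn14 knockout.

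The genes that TWEAK changed were followed into the knockouts as lists, over 12 camera tests. These lists were chosen on the TWEAK and WT libraries, so only the comparison between the knockouts does not contrast libraries that chose them. There, of the 773 genes that rose with TWEAK, 248 were higher and 315 lower in the Fn14 knockout than in the Fn14alpha knockout, where independent lists would share 237 and 220 (median −0.10, camera adjusted p = 0.170). The 119 of them with a log2 fold change of at least 1 were higher in 21 cases and lower in 58 (median −0.46, camera adjusted p = 1.21e-04, adjusted p = 0.0605 with an estimated correlation). The 328 genes that TWEAK lowered were higher in 136 cases and lower in 91 (median 0.08, camera adjusted p = 0.138), and 27 of them with a decrease of at least 1 were higher in 4 and lower in 11 (median −0.88, camera adjusted p = 0.0912).

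Against WT, the 119 genes were lower in 73 and higher in 20 cases in the Fn14 knockout (median −0.95, camera adjusted p = 8.27e-09, adjusted p = 0.0177 with an estimated correlation) and lower in 52 and higher in 25 in the Fn14alpha knockout (median −0.26, camera adjusted p = 0.0137, adjusted p = 0.183 with an estimated correlation). All 773 had medians of −0.08 in the Fn14 knockout (camera adjusted p = 0.0834) and −0.01 in the Fn14alpha knockout (adjusted p = 0.279). Unchanged groups simulated against the same WT libraries had medians of 0.01 in both, and with separate WT libraries for each step the medians ran from −0.16 to −0.12 and from −0.10 to −0.02. The 328 lowered genes had medians of −0.19 in the Fn14alpha knockout (camera adjusted p = 6.76e-04, adjusted p = 0.0659 with an estimated correlation) and −0.08 in the Fn14 knockout (adjusted p = 0.323), against simulated values of −0.04. With separate WT libraries these ran from −0.19 to −0.12 and from −0.03 to 0.09. The 27 strongly lowered genes had medians of −0.10 in the Fn14alpha knockout (adjusted p = 0.170) and −0.67 in the Fn14 knockout (adjusted p = 0.00736, adjusted p = 0.0316 with an estimated correlation). Unchanged groups gave −0.20 to −0.02 and −0.23 to 0.00 for such lists in simulation, and with separate WT libraries, which chose 17 to 43 genes, the medians ran from −0.56 to 0.13 and from −0.53 to −0.07; these do not reach −0.67. For the strongly induced genes unchanged groups gave 0.03 on average in the Fn14alpha knockout and 0.02 in the Fn14 knockout. With separate WT libraries the medians were −0.32 to −0.23 in the Fn14alpha knockout and −1.04 to −0.73 in the Fn14 knockout.

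Both knockouts shared changes relative to WT in part. Across 16029 genes, which are not independent replicates, their log2 fold changes correlated at r = 0.304 with a covariance of 0.226. Unchanged groups that share the WT libraries gave r = 0.490 and a covariance of 0.0201 in simulation, and with WT split the observed values were 0.246 to 0.287 and 0.195 to 0.217. Genes higher in both knockouts numbered 1220 (851.5 for independent lists) and genes lower in both 1433 (937). In opposite directions there were 730 genes higher in the Fn14alpha and lower in the Fn14 knockout (843.5 for independent lists) and 772 the other way (946). In the simulation 0 genes were called in both, and with WT split 749 to 870 were higher and 1079 to 1117 lower in both.

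**Figure D4:**
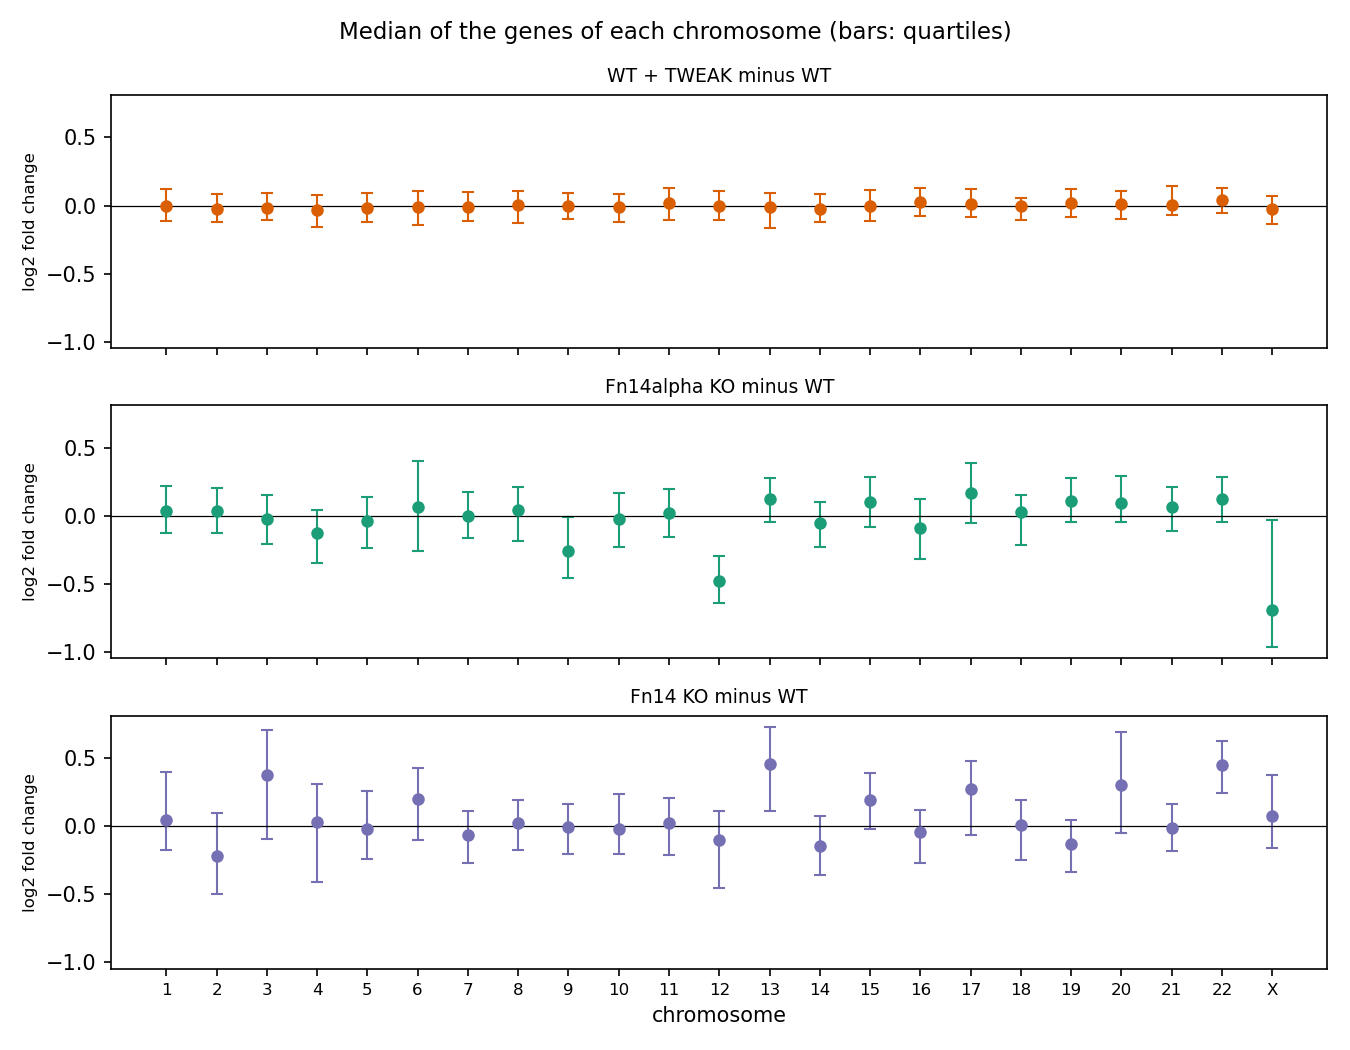
Median log2 fold change of the genes of each chromosome with at least 2 log2 CPM (points) with the quartiles of those genes (bars) in 3 comparisons. With TWEAK the medians lay near 0, in the Fn14alpha knockout X and chromosome 12 lay at −0.69 and −0.48, and in the Fn14 knockout chromosomes 13 and 22 lay at 0.45.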

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

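The tests on windows of neighbouring genes, on pseudogenes, on calls that passed in the same direction and on SDs without the trend with transcript length were chosen after the results they concern were seen, the pattern of NF-kB targets was chosen after its list result was seen in place of one on all TWEAK-induced genes, and the other tests were chosen before their results were seen.

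Chance assignment of libraries to groups was tested by refitting all 35 splits of the 8 libraries of each comparison into 4 and 4. In each comparison 1 of 35 splits, the labelled one, gave as many genes. The highest count among the other splits was 1 gene for TWEAK and 0 genes for the Fn14alpha knockout, the Fn14 knockout and the difference of the knockouts, against 1101, 6771, 8472 and 9489 genes. Every other split mixes libraries of both groups, so a real difference enters its spread and lowers its calls. The smallest share that these splits can give is 1 of 35. The labelled split stood out in each comparison, but these splits cannot exclude chance.

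The first pattern is that neighbouring genes moved together in the knockouts. Of 321 windows of 50 neighbouring genes, 97 in the Fn14alpha knockout and 138 in the Fn14 knockout had a median log2 fold change beyond 0.2, against at most 5 and 12 in 1000 shuffles of gene order and 0 windows with TWEAK, as copy number differences between the cultured lines could give. With the local median removed the counts of calls were 73.5% and 79.5% of the original, and 57.5% and 63.7% of the original calls passed in the same direction. That argues against shifts shared by neighbouring genes as the whole cause of the calls. Removing a shared median does not remove unequal responses of single genes or effects on genes elsewhere, so these stay open. With total counts in place of TMM 95.1% and 87.4% of the calls passed in the same direction. The share of higher calls moved by at most 5.65 and 14.3 percentage points with other scalings. Total counts shifted all genes nearly alike, by a median log2 of 0.033 and −0.117. The called genes had a median absolute log2 fold change of 0.494 and 0.568, so most calls had to pass. Most calls thus did not hang on the choice between TMM and total counts, but neither value decides whether scaling caused them. Loss of the receptor and descent of each line from other cells stay open, because genotype and line coincide.

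The next pattern is that WT replicate 4 and Fn14 knockout replicate 1 lay apart from the rest of their groups. Their deviations from the other libraries of their group had SDs of 0.263 and 0.313 across genes, against 0.128 to 0.231 in the other 14, and correlated with each other at 0.336 across genes, which are not independent replicates. Deviations had Spearman correlations with exonic size of −0.385 and −0.495. In size the first was passed by 0.457 in Fn14 knockout replicate 4 and 0.416 in Fn14alpha knockout replicate 1. By the rule on size set beforehand, WT replicate 4 was therefore not singled out. Those correlations were positive, however, and the lowest of the other 14 was −0.341, in Fn14alpha knockout replicate 3. A part played by transcript length thus stays open. Without the trend with exonic size the SDs were 0.242 and 0.273 against at most 0.207 in the others, which argues against transcript length as the whole cause. RNA or reads of one in the other are argued against by upper limits of 3.12% (1 gene, 0 of 118 counts) and 0.474% (8 genes). These limits cover counting error only, and the limit for WT replicate 4 rests on 1 gene. Pseudogenes had median deviations of 0.0860 in the Fn14 knockout library and 0.122 in WT replicate 4, above those of the other 14 (−0.0788 to 0.0708). Neither reached the 0.2 that was set for reads given to pseudogenes, and a smaller share of such reads stays open. No biological explanation was tested. Ribosomal protein genes were higher in both libraries, so RNA quality may differ. Their mean was 8.63 against 8.30 to 8.31 log2 CPM in WT and 8.65 against 8.11 to 8.28 in the Fn14 knockout.

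The last pattern is that NF-kB targets were lower in the Fn14 knockout than in the Fn14alpha knockout, with a median log2 difference of −1.46. It is not carried by chromosome-scale shifts, as the median was −1.54 after the local median was removed, nor by both libraries that lay apart, as it was −1.38 without them. A candidate explanation is that Fn14 forms left in the Fn14alpha knockout keep NF-kB targets higher, which is a hypothesis from these data. Counts per isoform and return of single Fn14 forms to the Fn14 knockout would test it, and neither was analysed here. Differences between the lines other than Fn14 stay open and were not tested.

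Of 411 groups of 4 libraries tested for 1 value apart, by the gap to the nearest other library as a share of the group's range, 35 exceeded the 95% critical value, where chance gives about 1 in 20, or 20.6. WT replicate 4 held 9 of them and Fn14 knockout replicate 1 held 6. In 10 the other 3 libraries had 0 counts and 1 library had 1 count, so that the share was 1: JCHAIN, SSX1, MGST1, CSF3 and TLX1 in the Fn14 knockout, PAGE1, SPANXB1 and ADAMTS2 in the Fn14alpha knockout, and S100A9 and S100A8 in WT.

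WT replicate 4 lay apart for ribosomal protein genes (0.984), ATF4 targets (0.883), FST (0.833), ICAM1 (0.847), EDN1 (0.832), HMGCS1 (0.894), MMP1 (0.921) and SQLE (0.853). Fn14 knockout replicate 1 lay apart for stellate cell matrix genes (0.854), adhesion molecules (0.888), mitochondrial mRNAs (0.859) and PSMB9 (0.870), and Fn14 knockout replicate 4 for TNFRSF12A (0.892). Mitochondrial mRNAs had a mean of 10.6 log2 CPM in Fn14 knockout replicate 1 against 11.3 to 11.4 in the other Fn14 knockout libraries. Other WT libraries lay apart for matrix-degrading enzymes (0.843, replicate 3), TRBC2 (0.956, replicate 3) and S1PR1 (0.948, replicate 1). TWEAK replicate 2 lay apart for immediate early genes (0.904) and ST6GALNAC5 (0.853). Fn14alpha knockout replicate 3 lay apart for chemokines and cytokines (0.865), S100A9 (0.907, at most 1 count per library), PCDHB17P (0.876) and ALDH1L2 (0.899), and replicate 4 for CCN2 (0.950), KIRREL2 (0.897) and UCA1 (0.861).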

How the results depend on the processing

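Removing the local median and leaving out both libraries that lay apart were chosen after the data had been seen. Across other scalings, filters, tests and fits, the counts of called genes stayed within 1.5 times of the counts reported, except with an absolute log2 fold change of at least 1 (146 for TWEAK, 1229 for the Fn14alpha knockout, 2071 for the Fn14 knockout and 2445 between the knockouts), where the stricter rule itself is the cause. The genes behind similar counts differed in part. Of the 1101 TWEAK calls, 740 were also called with limma on log2(FPKM + 0.1), 914 with total counts and 1096 with DESeq2 size factors. Of the 8472 Fn14 knockout calls these numbers were 5951, 7405 and 8381. The share of higher calls moved with scaling: with total counts TWEAK had 586 higher and 750 lower genes, against 773 and 328. Leaving out 1 of the 16 libraries gave 759 to 1604, 6038 to 7471, 8012 to 8867 and 8937 to 9852 genes. The highest TWEAK and Fn14alpha knockout counts came without Fn14 knockout replicate 1, and the highest count between the knockouts without WT replicate 4, although neither library is in the groups compared. For lists and named genes only libraries of the groups compared were left out. Of the values of named genes under the alternatives, 3171 kept direction and call, 10 lost the call and 0 reversed. Nearly all of these genes were picked for large differences or small adjusted p in the same data. List members that did not pass were left out, partly because they changed sign. Few losses and reversals therefore had to follow, and the counts do not speak for other genes.

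The replicate block gave 893, 6454, 8205 and 9241 genes, and 4 called lists between the knockouts in place of 7. The numbers did not pair the libraries: deviations of same-numbered libraries correlated between −0.228 and 0.108, above 0.1 in 1 of 24 pairs, and 5 libraries matched their own number best. Lists called for TWEAK, the Fn14alpha knockout, the Fn14 knockout and the difference numbered 4, 3, 4 and 2 with an estimated correlation and 13, 19, 21 and 15 with fry, which asks another question. Of all list tests under alternatives, 1197 kept direction and call, 61 gained a call, 40 lost one and 28 reversed, each of the last without a call in the value reported.

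Reversed camera adjusted p with the local median removed were 0.693 (histones, Fn14alpha knockout), 0.415 (hypoxia) and 0.880 (mitochondrial mRNAs) in the Fn14 knockout, and 0.755 (neighbours of TNFRSF12A, difference). Others were 0.975 for immediate early genes in the Fn14 knockout with the replicate block and 0.151 for ribosomal protein genes between the knockouts without both libraries apart. With fry they were 0.139 (cholangiocyte markers, Fn14alpha knockout) and 0.899, 0.384 and 0.371 (immediate early genes, quiescent stellate cell markers and cholangiocyte markers, difference). Leaving out 1 library gave, for lists that reversed in part of these fits, 0.521 to 0.971 (cell cycle, TWEAK) and 0.855 to 0.991 (list cholangiocyte and epithelial markers, Fn14alpha_KO). In the Fn14 knockout these were 0.815 to 0.997 (immediate early genes), 0.199 to 0.997 (mitochondrial mRNAs), 0.235 to 0.818 (histones) and 0.00738 (without Fn14 knockout replicate 1) to 0.997 (ribosomal protein genes). Between the knockouts ribosomal protein genes had 0.253 to 0.841. The cause was not tested for any of these.

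TWEAK-induced genes between the knockouts had a median of −0.46 (−0.4634) for genes with a change of at least 1 and between −0.114 and −0.05968 (without Fn14 knockout replicate 1) under the other alternatives, against −0.1002. TWEAK-lowered genes had −0.8826 there, a reversal, and 0.08973 with no filter. The cause was not tested. The median of TWEAK-higher genes, Fn14alpha_KO, ran from −0.02047 to 0.001879 with 1 library left out, the latter a reversal without Fn14alpha knockout replicate 3. The correlation of the knockouts was 0.2675 with WT split, and the covariance 0.2067 with WT split, 0.3144 over called genes, 0.196 with the local median removed and 0.2324 to 0.2507 with 1 library left out. Depth limits the ratios of genes with 0 to 3 counts in a group, for which only a bound or a counting interval is given.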

Other observations

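The tests of 1276 Gene Ontology terms, with a preset and an estimated correlation, were chosen after the data had been seen. In the Fn14 knockout, genes annotated to calcium-dependent adhesion between cells were lower in 17 of 26 cases and higher in 2, with a median log2 fold change of −1.25 (limma's camera, adjusted p = 0.00172, adjusted p = 0.623 with an estimated correlation). Genes of cytokine-mediated signalling were lower in 43 of 71 cases and higher in 8 (median −0.58, camera adjusted p = 0.00172, adjusted p = 0.623 with an estimated correlation). With TWEAK, genes that promote the inflammatory response were higher in 16 of 48 cases and lower in 1 (camera adjusted p = 2.59e-04, adjusted p = 0.0297 with an estimated correlation). Genes of fatty acid beta-oxidation had a median of −0.12 with TWEAK, with 2 of 42 lower and 0 higher (camera adjusted p = 0.00588, adjusted p = 0.532 with an estimated correlation). Genes of cholesterol synthesis were lower in 22 of 34 cases and higher in 4 in the Fn14alpha knockout (camera adjusted p = 0.00783, adjusted p = 0.997 with an estimated correlation), and between the knockouts higher in 22 and lower in 5 (camera adjusted p = 0.0171, adjusted p = 0.992 with an estimated correlation). Of the terms given here only that on the inflammatory response kept its call with an estimated correlation. Members of such terms overlap with each other and with the lists above.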
